A study of Mus musculus with 9 samples.

How the data were processed

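RNA of sorted esophageal epithelial cells of wild-type mice was measured by m6A immunoprecipitation followed by sequencing. Per the labels' protocols, part of the RNA was kept as Input, the rest was incubated for 2 h at 4 °C with 1.25 µg of anti-m6A antibody per reaction on magnetic beads, the washes were kept as Unbound, and bound RNA was eluted with 20 mM of a free m6A nucleotide. Libraries were made with a low-input kit and sequenced as paired reads of 150 nt, with 3 biological replicates per fraction per the labels. Whether libraries of the same number share their RNA is not stated in the labels.

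The submitters' processing notes name cutadapt 3.3, STAR 2.7.9a, featureCounts and DESeq2, and the builds mm10 and GRCm38, without saying which step each served. The one file analysed holds no values per library. It is the authors' deposited table of a comparison, with a p-value, an adjusted p-value, a t statistic (a score without a fixed range) and a log2 fold change for each gene. The groups compared, their direction and the way the table was made are not given in the sources used here. The tests per fraction that had been laid out before the data were examined need values per library of all genes and the fraction of each library. The authors' values are therefore described. Tests were redone only as checks, on recovered values or, for Student's p and the scaling to a median, from the deposited t, p and log2 fold change of the genes.

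What the deposited table holds was worked out from its values. Solving t and p for the degrees of freedom gave 2 to 4 for every gene (median 2.46), the range of an unequal-variance test of 3 libraries against 3. The deposited adjusted p-values equal a Benjamini-Hochberg adjustment over the 18779 genes with a p-value within 3.3e-15, and t and log2 fold change had the same sign in all 18779. The other 1214 genes have a log2 fold change of 0. Degrees of freedom of exactly 2 mark the 3054 genes with one group at zero, 2084 of them at zero in the second and 970 in the first group, and 2120 of these have reads in 1 library.

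Small RNA genes with reads in 1 library, multiplied by their length, fell on levels that are whole fractions of 6 numbers, which gave the 6 library totals, each within 0.0014 of a whole number. The values behind the test are thus reads divided by gene length and library total, on a linear scale, and the log2 fold change is that of the group means plus 1. In a gene of 2000 nt 1 read is worth 37.2 to 53.0 in these units, so the added 1 is far less than 1 read, and a fold change against a group at zero is set by it. For such genes the fold is given against a floor of 3 reads over the group at zero. The reads of the other group are taken as exact there, so this fold is not a lower bound.

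With the totals known, whole reads per library were searched that return a gene's t, degrees of freedom and log2 fold change within 1e-09, for genes with at most 200 reads in every library. They were found for 8697 genes (46.3%), of which 7763 have reads in both groups. Values are fixed by this, but reads only up to a common factor, and the smallest solution is given as "at least". Of 236 small RNA genes recovered, 231 had a length equal to their span in RefSeq. On a simulated table of 18779 genes with the same library totals, 254 of 283 genes with at most 200 reads were recovered with their true values. The true reads came back for 249, and 0 of the 600 genes tried gave wrong values.

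In that simulation 100 genes changed 2-fold and 100 changed 4-fold at a dispersion of 0.05, and the authors' kind of test with adjustment called 0 of the former and 1 of the latter, with 0 of the unchanged genes. An unadjusted p under 0.05 was reached by 50 of the former and 71 of the latter. Only 200 of the 18779 simulated genes changed, and the dispersion and the levels of genes without recovered reads were assumed. The cut-off after adjustment depends on the share of genes that change, and 33.9% were called in the authors' deposited table. These counts therefore do not measure the power of the deposited comparison. The labels state biological replicates without naming animals, so p-values measure the spread between these libraries. With equal reads in 1 group and none in the other, that spread comes from the library totals alone. PCR duplicates carry no molecular identifiers, so the floor for a group at zero covers counting error only. Wilson intervals are over called genes and bootstrap intervals over genes. Both take genes as independent, and neither measures counting error or the spread between libraries.

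Gene names were matched to the RefSeq table of GRCm38.p6, 19540 by symbol, 103 by a synonym and 350 not at all, and coordinates are those of GRCm38.p6. Reads shared between near-identical genes, such as histone genes, Zfp genes and pseudogenes of ribosomal protein genes, could be divided in ways the table does not show. 33 gene lists were fixed before the data were examined. Of these, mitochondrially encoded genes, sought by symbols starting with mt-, had 0 members in the table, and m6A erasers were too few for the list test. The other 31 were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed normal score of the deposited p-value, with a preset correlation of 0.01, two-sided, and Benjamini-Hochberg adjustment over the 31 lists. A correlation estimated from libraries, and fry, need values per library of all members and were not run, so preset correlations of 0.05 and 0.1 were used. List medians are over members with reads in both groups.

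Named genes are the 8 largest and 8 smallest log2 fold changes among genes with adjusted p under 0.05, without predicted or unnamed genes, up to 3 called members of each list in its majority direction and up to 2 in the other, and all writers, erasers and readers. Ordering by mean level was not possible, so members were ordered by adjusted p, and some are left out of the text for length. Genes looked up outside this rule are said to be so. Fold changes are shown as deposited, and scaling to the median multiplied the second group by 2 to that median. Group variances follow from t and the degrees of freedom up to which group holds which, so both orders were computed where values were not recovered. Other alternatives were Student's p from the same t, stricter thresholds, genes with reads in both groups, genes of these without recovered reads, leaving out each library, a log2 scale with pseudocounts of 0.1, 1 and 10, and the 10 splits of 6 libraries. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.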

Results

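RNA from EpCAM-positive, CD45-negative epithelial cells of the wild-type mouse esophagus was divided by immunoprecipitation with an antibody against N6-methyladenosine (m6A), the methyl mark placed on adenosines of RNA by the METTL3/METTL14 complex. The labels give 9 libraries in 3 groups of 3: Input RNA set aside before the precipitation, m6A-bound RNA eluted from the antibody, and Unbound RNA from the washes. The stated aim was to find transcripts that the complex could regulate in the adult esophageal epithelium. The file analysed here is the authors' deposited table of 1 comparison over 19993 genes, of which 18779 have a p-value. It compares 2 groups of 3 libraries but names neither. The group with the higher mean at a positive log2 fold change is called the first group here, and the other the second group. The library totals behind the table's values were 13428545, 12360365 and 11381926 reads in the first group and 12843331, 10238371 and 9442826 in the second.

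In the authors' deposited table, transcripts of zinc finger proteins, chromatin regulators and the m6A writer complex were higher in the first group, and transcripts of ribosomal proteins, the respiratory chain and the proteasome were higher in the second. Of the 18779 genes with a p-value in the authors' deposited table, 6359 (33.9%) had an adjusted p under 0.05, 4543 of them with a positive and 1816 with a negative log2 fold change. These genes are referred to as called. The median log2 fold change in the authors' deposited table over the 15725 genes with reads in both groups was 0.96 with quartiles of -0.31 and 2.2. List medians are therefore also given as their distance from 0.96. When the second group was scaled up by this median, the share of positive calls went from 71.4% to 49.2% or 28.9%. The first choice gives the larger variance to the group with the higher mean, the second to that with the lower mean. Each was applied at once to all genes where the table leaves this open, though genes may differ. Of 1632 called genes with reads in both groups and recovered values, 76.6% followed the first choice. Calls after this scaling are given for both choices, in that order. With it 80 or 82 ribosomal protein genes and 86 or 85 oxidative phosphorylation genes were called negative. Positive calls then numbered 185 or 103 among Zfp genes, 29 or 9 among chromatin regulators, 7 or 2 among m6A writers and 4 or 1 among readers. Of 31 gene lists tested with limma's cameraPR against all other genes, 21 had an adjusted p under 0.05 with a preset correlation of 0.01 between genes, and 9 with a correlation of 0.05. With a correlation of 0.1 only the lists of ribosomal proteins, oxidative phosphorylation and the proteasome kept it, all lower in the first group. Zfp genes then had adjusted p = 0.072, chromatin regulators adjusted p = 0.061 and m6A writers adjusted p = 0.057.

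Genes of the cytosolic ribosome formed the list with the lowest values. Of 85 ribosomal protein genes 79 were called in the authors' deposited table, all with negative log2 fold changes. The count was 81 when adjusted over the list alone. Their median of -2.77 in the authors' deposited table lay 3.73 below that of all genes (cameraPR, adjusted p = 1.7e-45). Examples from the authors' deposited table are Rps15a (chromosome 7, 118104374 to 118116147) at -3.22 (adjusted p = 0.00016), Rps23 at -3.18 (adjusted p = 0.00027) and Rpl34 at -2.87 (adjusted p = 0.00064). Nuclear genes of oxidative phosphorylation, which encode subunits and assembly factors of the respiratory chain, were called negative in 82 of 92 cases and positive in 3 in the authors' deposited table. These counts were 84 and 4 when adjusted over the list alone. Their median of -2.29 in the authors' deposited table was 3.25 below that of all genes (cameraPR, adjusted p = 4.7e-43). Among them in the authors' deposited table, Atp5mc2 was at -3.3 (adjusted p = 0.00064), Cox5a at -2.75 (adjusted p = 0.00062) and Atp5f1b at -1.38 (adjusted p = 0.0003). On the other side of the authors' deposited table were Ndufaf4, a complex I assembly factor, at 2.95 (adjusted p = 0.0075) and Ndufs1 at 0.66 (adjusted p = 0.013). Ndufs1 lies 0.3 below the median of all genes and thus on the other side after scaling to it.

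Proteasome subunit genes showed the same direction, with 24 of 38 called negative and 6 positive in the authors' deposited table. They numbered 25 and 6 when adjusted over the list alone. The median of this list in the authors' deposited table was -1.37 (cameraPR, adjusted p = 1.1e-12). Psmd8 stood at -1.54 (adjusted p = 0.0003), Psmb7 at -1.56 (adjusted p = 0.0013) and Psma5 at -1.88 (adjusted p = 0.0014) in the authors' deposited table, whereas Psmd5 stood at 2.0 (adjusted p = 0.0031). Psmc6 was called at 0.38 (adjusted p = 0.0094) in the authors' deposited table, which is 0.58 below the median of all genes. After scaling to the median 28 or 29 proteasome genes were negative and 2 or 1 positive. Translation initiation and elongation factors were divided: 20 of 38 were called negative and 8 positive in the authors' deposited table. They numbered 20 and 12 when adjusted over the list alone, and 23 and 4 or 23 and 2 after scaling to the median. For these factors cameraPR placed the list on the lower side (adjusted p = 5.8e-05). Eif3i at -2.15 (adjusted p = 0.0032), Eif1ax at -1.59 (adjusted p = 0.0032) and Eif3g at -1.44 (adjusted p = 0.0035) were negative in the authors' deposited table. Eif3a, the large scaffold subunit of eIF3, was positive at 3.56 (adjusted p = 0.0036) in the authors' deposited table, as was Eif4g3 at 2.93 (adjusted p = 0.0037).

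The list with the highest median was that of the Zfp genes, most of which encode DNA-binding zinc finger proteins. Of 364 such genes 229 were called positive and 7 negative in the authors' deposited table. They numbered 277 and 8 when adjusted over the list alone. The median over the 338 with reads in both groups of the authors' deposited table was 3.13, or 2.17 above that of all genes (cameraPR, adjusted p = 2.5e-11). Zfp800 at 3.88 (adjusted p = 0.00019), Zfp507 at 3.08 (adjusted p = 0.0014) and Zfp667 at 2.99 (adjusted p = 0.0017) had the smallest adjusted p of the list in the authors' deposited table. The negative members of the authors' deposited table included Zfp467 at -2.05 (adjusted p = 0.0073) and Zfp593 at -1.35 (adjusted p = 0.0052). Chromatin regulators were called positive in 37 of 54 cases and negative in 1 in the authors' deposited table, with a median of 2.37. They numbered 48 and 1 when adjusted over the list alone. Against all other genes cameraPR gave adjusted p = 1.1e-06. The histone demethylase gene Kdm5b stood at 2.67 (adjusted p = 0.0024), the corepressor gene Ncor1 at 3.28 (adjusted p = 0.0054) and the histone methyltransferase gene Kmt2d at 2.33 (adjusted p = 0.006) in the authors' deposited table. The negative call in this list of the authors' deposited table was the deacetylase gene Hdac5 at -0.41 (adjusted p = 0.033).

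**Figure D1:**
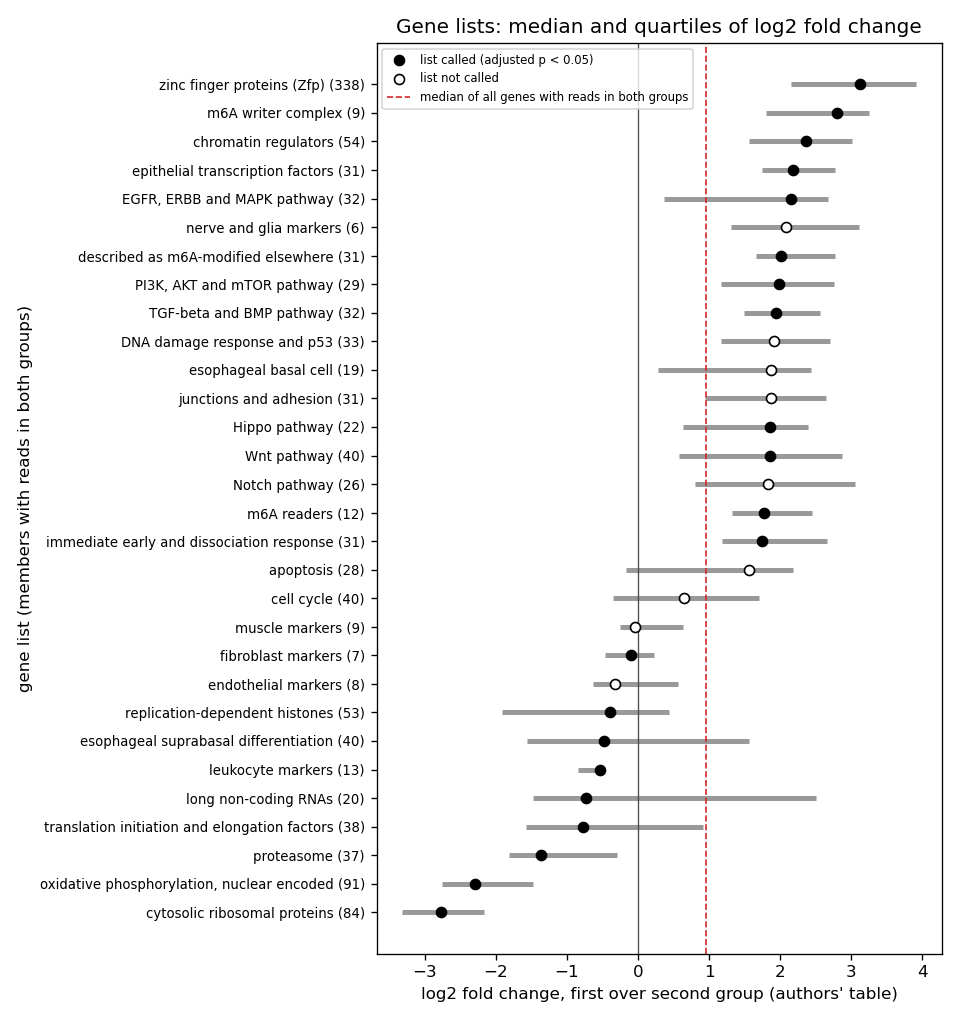
Median (points) and quartiles (bars) of the log2 fold change of the first over the second group in the authors' deposited table, for each gene list with at least 5 members that have reads in both groups, whose number is in parentheses. Filled points are lists called by cameraPR, and the dashed line is the median of 0.96 over all genes with reads in both groups: ribosomal protein genes lie lowest at -2.77 and Zfp genes highest at 3.13.

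Genes of the m6A machinery were mostly on the positive side. Of 9 writer genes 8 were called in the authors' deposited table, all positive, with a median of 2.81. All 9 were called when adjusted over the list alone. For the writers cameraPR gave adjusted p = 0.0019, and adjusted p = 0.19 on log2 fold changes in place of scores. The scaffold gene Zc3h13 (chromosome 14, 75284306 to 75344433) stood at 4.02 (adjusted p = 0.0097), Rbm15b at 3.42 (adjusted p = 0.0027), Rbm15 at 3.26 (adjusted p = 0.041) and Virma at 2.81 (adjusted p = 0.031) in the authors' deposited table. Cbll1 was at 2.24 (adjusted p = 0.035), Mettl16 at 1.72 (adjusted p = 0.0063) and Mettl14, the partner of Mettl3, at 1.8 (adjusted p = 0.012) in the authors' deposited table. Wtap had 2.83 in the authors' deposited table and was not called (adjusted p = 0.062). Mettl3, the catalytic subunit, was called at 0.86 (adjusted p = 0.0016) in the authors' deposited table. It lay 0.1 below the median of all genes and was not called after scaling to it (adjusted p = 0.074 or 0.17). Virma (0.029 or 0.13), Rbm15 (0.04 or 0.16), Cbll1 (0.041 or 0.18), Mettl14 (0.014 or 0.086) and Mettl16 (0.02 or 0.086) lost their calls after this scaling under the second order of the variances only. The erasers Fto at 0.54 (adjusted p = 0.41) and Alkbh5 at 1.23 (adjusted p = 0.086) were not called in the authors' deposited table. Adjusted over the list alone the count was also 0, against 1 at an unadjusted p under 0.05, and Fto lay 0.42 below the median of all genes.

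Reader genes were called positive in 8 of 12 cases and negative in 1 in the authors' deposited table, with a median of 1.77. They numbered 9 and 1 when adjusted over the list alone. For the readers cameraPR gave adjusted p = 0.041, adjusted p = 0.11 with a correlation of 0.05, and adjusted p = 0.47 on log2 fold changes in place of scores. The YTH-domain genes all had positive values in the authors' deposited table: Ythdf2 3.67 (adjusted p = 0.01), Ythdf3 3.38 (adjusted p = 0.044), Ythdc1 2.93 (adjusted p = 0.025), Ythdc2 2.05 (adjusted p = 0.0088) and Ythdf1 1.75 (adjusted p = 0.02). Igf2bp2 at 2.28 (adjusted p = 0.039), Fmr1 at 1.72 (adjusted p = 0.016) and Hnrnpa2b1 at 1.16 (adjusted p = 0.0057) were also called in the authors' deposited table. After scaling to the median, Igf2bp2 (adjusted p = 0.1 or 0.13), Hnrnpa2b1 (0.24 or 0.33), Ythdc2 (0.063 or 0.079) and Ythdf3 (0.053 or 0.15) were not called under either order of the variances. Ythdf1 (0.027 or 0.14), Ythdc1 (0.023 or 0.095) and Fmr1 (0.023 or 0.13) were not called under the second. Hnrnpc was called negative at -0.81 (adjusted p = 0.037) in the authors' deposited table. Igf2bp3 at 1.79 (adjusted p = 0.063), Prrc2a at 1.38 (adjusted p = 0.13) and Igf2bp1 at -0.31 (adjusted p = 0.89) were not called in the authors' deposited table. Of 31 transcripts described as m6A-modified in other mouse or human cells, 16 were called positive and 0 negative in the authors' deposited table, with a median of 2.01. Calls numbered 20 and 0 when adjusted over the list alone, and 14 and 0 or 5 and 0 after scaling to the median. For this list cameraPR gave adjusted p = 0.0019, and adjusted p = 0.16 on log2 fold changes in place of scores. Called members of the authors' deposited table include Jun at 2.8 (adjusted p = 0.0069), Bcl2 at 2.76 (adjusted p = 0.0069) and Smad7 at 2.44 (adjusted p = 0.0075).

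**Figure D2:**
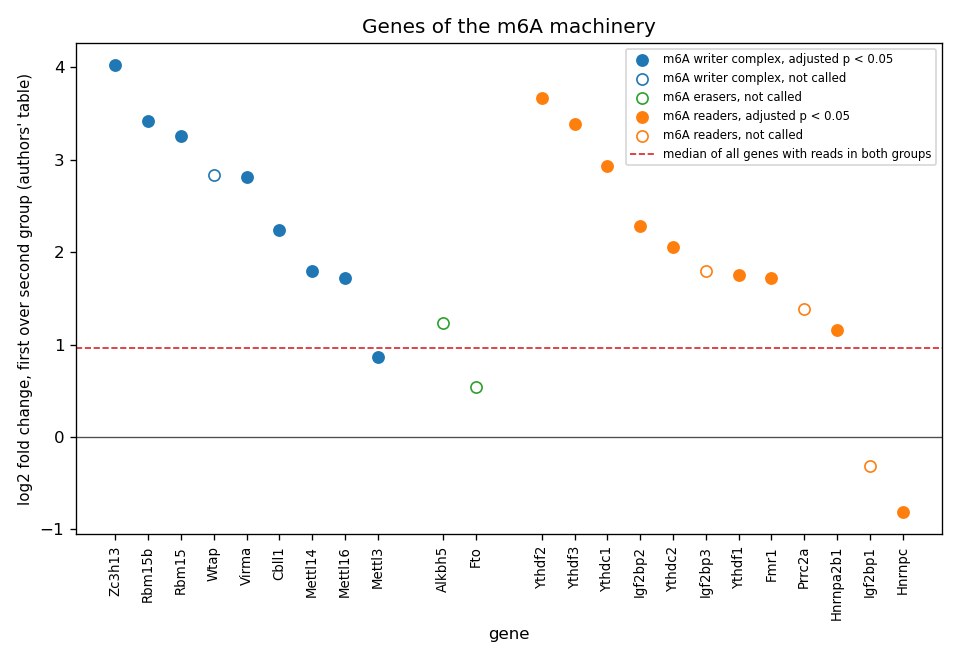
Log2 fold change of the first over the second group in the authors' deposited table for 9 writer, 2 eraser and 12 reader genes of m6A, filled where the table's adjusted p is under 0.05. The dashed line is the median of 0.96 over all genes with reads in both groups: Zc3h13 lies highest at 4.02, and Mettl3 at 0.86 lies below the line.

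Signalling lists were on the positive side with calls in part of their members. For comparison, 4225 of 14921 protein-coding genes with a p-value were called positive in the authors' deposited table. Among the 7962 genes with reads in both groups and none recovered, 3050 were called positive. The shares of Wnt, EGFR, immediate early and Notch genes given below are close to this last one. TGF-beta and BMP genes were called positive in 16 of 34 cases and negative in 0 in the authors' deposited table. Calls were 20 and 0 when adjusted over the list alone. The authors' deposited table has Bmp2 at 3.73 (adjusted p = 0.0012) and Acvr1 at 2.72 (adjusted p = 0.0049). PI3K, AKT and mTOR genes were called positive in 15 of 29 cases in the authors' deposited table, and in 18 when adjusted over the list alone. Values in the authors' deposited table were those of Rps6kb1, which encodes S6 kinase, at 3.48 (adjusted p = 0.00088), Phlpp2 at 3.0 (adjusted p = 0.0052) and Mtor at 1.59 (adjusted p = 0.0048). Wnt genes were called positive in 16 of 42 cases in the authors' deposited table. Adjusted over the list alone, 21 were positive and 2 negative. Called Wnt genes of the authors' deposited table include Apc at 3.51 (adjusted p = 0.012), Fzd3 at 2.87 (adjusted p = 0.0037) and the gene of beta-catenin, Ctnnb1, at 1.98 (adjusted p = 0.012). Hippo genes were called positive in 10 of 23 cases in the authors' deposited table, and in 13 when adjusted over the list alone. Among them in the authors' deposited table were Amotl2 at 2.75 (adjusted p = 0.009), Tead1 at 1.98 (adjusted p = 0.011) and Stk4 at 1.96 (adjusted p = 0.0062). EGFR, ERBB and MAPK genes were called positive in 12 of 33 cases and negative in 2 in the authors' deposited table. These became 21 and 2 when adjusted over the list alone. Their examples in the authors' deposited table are Braf at 2.94 (adjusted p = 0.013), the EGFR ligand gene Hbegf at 2.53 (adjusted p = 0.0015), and on the negative side Mapk3 at -1.37 (adjusted p = 0.035) and Map2k2 at -1.17 (adjusted p = 0.044). Immediate early genes were called positive in 12 of 31 cases and negative in 1, Nfkbia at -1.18 (adjusted p = 0.049), in the authors' deposited table. These became 13 and 1 when adjusted over the list alone. Relative to all other genes, cameraPR gave adjusted p of 0.0067 for TGF-beta and BMP and for PI3K, 0.017 for Hippo, 0.019 for EGFR, 0.026 for immediate early and 0.036 for Wnt genes. With a correlation of 0.05 these became adjusted p = 0.076, 0.073, 0.089, 0.11, 0.13 and 0.17, in the order TGF-beta, PI3K, Hippo, EGFR, immediate early and Wnt. On log2 fold changes in place of scores they were 0.28, 0.26, 0.52, 0.28, 0.32 and 0.47 in this order, so none was called. Over genes with reads in both groups the immediate early and Wnt lists each had adjusted p = 0.051. Notch genes were called positive in 10 of 30 cases and negative in 2 in the authors' deposited table. These became 13 and 2 when adjusted over the list alone, and the list was not called (cameraPR, adjusted p = 0.095). Over genes with reads in both groups its adjusted p was 0.043. Among them in the authors' deposited table were the sheddase genes Adam17 at 3.29 (adjusted p = 0.00095) and Adam10 at 2.64 (adjusted p = 0.017), and the glycosyltransferase gene Lfng at -2.09 (adjusted p = 0.049). After scaling to the median, positive and negative calls were 14 and 2 or 5 and 1 for TGF-beta and BMP genes and 11 and 2 or 4 and 4 for PI3K genes. They were 14 and 3 or 4 and 2 for Wnt genes, 9 and 0 or 1 and 0 for Hippo genes and 9 and 4 or 3 and 2 for EGFR genes. For immediate early genes they were 7 and 2 or 1 and 2, and for Notch genes 7 and 2 or 2 and 1. Of the genes named here, Mtor (adjusted p = 0.054 or 0.082) and Lfng (0.051 or 0.064) lost their calls under both orders of the variances. Stk4 (0.07), Tead1 (0.098), Ctnnb1 (0.052) and Adam10 (0.064) lost theirs under the second only.

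The epithelial lists were mixed. Epithelial transcription factors were called positive in 13 of 31 cases and negative in 1 in the authors' deposited table, with a median of 2.19. Calls were 14 and 1 when adjusted over the list alone, and 11 and 2 or 2 and 2 after scaling to the median. For this list cameraPR gave adjusted p = 0.0045, and adjusted p = 0.067 with a correlation of 0.05. Nfe2l2 at 3.81 (adjusted p = 0.012), Grhl2 at 2.72 (adjusted p = 0.012) and Foxa1 at 2.01 (adjusted p = 0.0099) were positive in the authors' deposited table, and Hopx at -1.85 (adjusted p = 0.029) was negative. Basal cell genes were called positive in 7 of 19 cases and negative in 2 in the authors' deposited table. Calls were 12 and 3 when adjusted over the list alone. After scaling to the median they were 6 and 3 or 0 and 5, so the balance turned under the second order of the variances, and the list was not called (cameraPR, adjusted p = 0.48). Bcl11b at 3.39 (adjusted p = 0.027), the integrin gene Itga3 at 2.5 (adjusted p = 0.023) and Sox2 at 1.8 (adjusted p = 0.015) were positive in the authors' deposited table. In the authors' deposited table Krt14 at -1.75 (adjusted p = 0.011) and Igfbp2 at -2.31 (adjusted p = 0.029) were negative. Suprabasal genes were called positive in 2 of 41 cases and negative in 2 in the authors' deposited table, with a median of -0.48. Calls were 0 and 1 when adjusted over the list alone, and 2 and 5 or 0 and 10 after scaling to the median. On the lower side cameraPR gave adjusted p = 0.031, and adjusted p = 0.16 with a correlation of 0.05. The plakin gene Ppl at 3.58 (adjusted p = 0.034) and Calml3 at 2.86 (adjusted p = 0.036) stood against Cstb at -2.96 (adjusted p = 0.011) and the cornified envelope gene Sprr2a1 at -2.11 (adjusted p = 0.017) in the authors' deposited table. Junction genes were called positive in 11 of 31 cases in the authors' deposited table, with Itgb6 at 2.37 (adjusted p = 0.0037). Negative calls of the authors' deposited table were 2, Jup at -1.4 (adjusted p = 0.02) and Perp at -0.56 (adjusted p = 0.036). The counts were 17 and 2 when adjusted over the list alone (cameraPR, adjusted p = 0.059), and 9 and 3 or 2 and 4 after scaling to the median. Krt5 at -0.89 (adjusted p = 0.086), Krt13 at -0.53 (adjusted p = 0.09), Krt4 at 0.97 (adjusted p = 0.21) and the sorting marker gene Epcam at -0.68 (adjusted p = 0.13), looked up after the values were seen, were not called in the authors' deposited table. After scaling to the median, Krt13 was called negative under both orders of the variances (adjusted p = 0.029 or 0.017). Krt5 (0.056 or 0.0073) and Epcam (0.053 or 0.027) were called negative under the second only. Under the second order Sox2 (0.1), Itga3 (0.11), Bcl11b (0.094), Ppl (0.12) and Calml3 (0.16) lost their calls. Foxa1 (0.057 or 0.11) lost its call under both orders.

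Cell cycle genes had few calls, 3 of 40 positive and 1 negative in the authors' deposited table. Calls were 1 and 1 when adjusted over the list alone (cameraPR, adjusted p = 0.42), and 1 and 3 or 1 and 7 after scaling to the median. Their median of 0.65 in the authors' deposited table is positive but lies 0.31 below that of all genes. E2f3 at 2.34 (adjusted p = 0.0097) and Cdk4 at -2.48 (adjusted p = 0.0044) had the smallest adjusted p on either side of this list in the authors' deposited table. DNA damage genes were called positive in 14 of 33 cases and negative in 2 in the authors' deposited table. Calls were 17 and 3 when adjusted over the list alone (cameraPR, adjusted p = 0.059), and 8 and 4 or 2 and 4 after scaling to the median. The p53 regulator gene Mdm2 stood at 3.6 (adjusted p = 0.017) and Rad50 at 3.64 (adjusted p = 0.012), whereas Trp53, the gene of p53 itself, stood at -1.14 (adjusted p = 0.0077) in the authors' deposited table. Apoptosis genes were called positive in 13 of 28 cases and negative in 3 in the authors' deposited table. Calls were 16 and 6 when adjusted over the list alone (cameraPR, adjusted p = 0.34), and 11 and 7 or 6 and 8 after scaling to the median. The authors' deposited table has Bid at 4.56 (adjusted p = 0.0032), Casp8 at 2.09 (adjusted p = 0.0032), Diablo at -1.82 (adjusted p = 0.00076) and Bax at -1.43 (adjusted p = 0.011).

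Non-coding and histone transcripts also went both ways. Of 24 long non-coding RNA genes in the list, 5 were called positive and 5 negative in the authors' deposited table. These became 5 and 10 when adjusted over the list alone, and 5 and 8 or 1 and 10 after scaling to the median. On the lower side cameraPR gave adjusted p = 0.0067, and adjusted p = 0.067 with a correlation of 0.05. Malat1 (chromosome 19, 5795690 to 5802672) at 3.27 (adjusted p = 0.0089), Norad at 3.38 (adjusted p = 0.018) and Neat1 at 2.9 (adjusted p = 0.02) were positive in the authors' deposited table. After scaling to the median, Norad (0.017 or 0.059) and Neat1 (0.019 or 0.075) lost their calls under the second order of the variances only. The small nuclear RNA gene Rn7sk at -3.84 (adjusted p = 0.0083) and the snoRNA host gene Snhg8 at -2.62 (adjusted p = 0.0089) were negative in the authors' deposited table. Replication-dependent histone genes were called positive in 2 of 65 cases and negative in 3 in the authors' deposited table, with a median of -0.39. These became 1 and 1 when adjusted over the list alone (cameraPR for the lower side, adjusted p = 0.00028), and 2 and 7 or 2 and 6 after scaling to the median. H1f2 at 3.49 (adjusted p = 0.026), H2bc21 at 2.93 (adjusted p = 0.005) and H4c8 at -3.07 (adjusted p = 0.01) were among the calls of the authors' deposited table. No symbol in the table starts with mt-, the only prefix by which mitochondrially encoded genes were sought.

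Markers of other cell types gave few calls. Of 19 leukocyte markers 1 was called in the authors' deposited table, the antigen presentation gene H2-Ab1 at -2.78 (adjusted p = 0.035). None was called when adjusted over the list alone, 2 or 3 were called negative after scaling to the median, and 6 are at zero in one group. On the lower side cameraPR gave adjusted p = 0.016, and adjusted p = 0.077 with a correlation of 0.05. Over genes with reads in both groups the list had adjusted p = 0.017, and over those without recovered reads 0.1. Ptprc, which encodes the CD45 protein used to exclude leukocytes and was looked up after the values were seen, was at 1.05 (adjusted p = 0.48) in the authors' deposited table. Of 11 endothelial markers 1 was called in the authors' deposited table, Egfl7 at -2.11 (adjusted p = 0.014). The count was also 1 when adjusted over the list alone (cameraPR, adjusted p = 0.058). Fibroblast markers had 0 calls among 11 in the authors' deposited table and when adjusted over the list alone, and 2 negative calls after scaling to the median under either order. On the lower side cameraPR gave adjusted p = 0.036, and adjusted p = 0.1 with a correlation of 0.05. Of the fibroblast markers 4 are at zero in one group. Over genes with reads in both groups the list had adjusted p = 0.13, and over those without recovered reads 0.32. There were also 0 calls in the authors' deposited table among 12 muscle markers (cameraPR, adjusted p = 0.26), 8 nerve and glia markers (adjusted p = 0.61) and 4 red blood cell markers (adjusted p = 0.26, and 0.014 on log2 fold changes), before and after adjustment over the list alone. At an unadjusted p under 0.05 the authors' deposited table has 1 fibroblast marker, 2 muscle markers and 0 of the nerve, glia and red blood cell markers.

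The largest positive fold changes belonged to genes with few recovered reads. The 8 largest positive values among called genes with established names were those of Nexn, Mexis, Unc93a2, Prss12, Zc2hc1c, Zfp184, Nck2 and Zfp941, each at zero in all libraries of the second group of the authors' deposited table. For Nexn, an actin-binding protein gene, at least 4, 5 and 4 reads in the first group lie behind the value in the authors' deposited table. Against a floor of 3 reads over the second group this is 3.79-fold higher if the reads of the first group are exact. For Zc2hc1c these were at least 8, 8 and 7 reads, which is 6.71-fold higher on the same terms. On the negative side H2bc12, with at least 4, 3 and 2 reads in the second group, Tmem37 and Mfng were at zero in the first group of the authors' deposited table. Tmem37 and Mfng each had at least 1, 1 and 1 reads in the second group, only 1.14-fold higher against the floor even if these reads are exact. Their adjusted p of 0.031 in the authors' deposited table thus rests on differing library totals, not on a spread of reads. Slc35f3 at -5.18 (adjusted p = 0.029), Cox8a at -4.38 (adjusted p = 0.0086) and Siva1 at -4.13 (adjusted p = 0.03) followed in the authors' deposited table. Next in the authors' deposited table were Pgls at -4.07 (adjusted p = 0.025) and the mitochondrial outer membrane protein gene Tspo at -4.06 (adjusted p = 0.015). For Slc35f3 the reads were at least 0, 0 and 1 in the first and 17, 11 and 9 in the second group, so the size of its value rests on few reads. No reads were recovered for Cox8a, Siva1, Pgls and Tspo, so few reads are not shown for them. Among called genes with reads in both groups, a set chosen after the values were seen, the largest positive values of the authors' deposited table were those of Cdc42ep2 at 6.3 (adjusted p = 0.025), Zfp354a at 6.05 (adjusted p = 0.012), Zfp991 at 5.59 (adjusted p = 0.037) and Ntm at 5.55 (adjusted p = 0.045). Behind the second group of these values lie few reads, at least 1, 0 and 0 for Cdc42ep2, 0, 0 and 1 for Zfp354a, 4, 0 and 2 for Zfp991 and 3, 0 and 0 for Ntm, so their size is uncertain. Of the 6359 calls in the authors' deposited table, 60 have one group at zero, and the median total behind these is at least 3 reads over 6 libraries.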

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

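Scaling to a median, filters on reads, other correlations and other list statistics were chosen after the data were seen. The tests per fraction were not run because the fraction of each library is not given. The normalizations of counts, fry and the estimated correlation were not run because values per library were recovered for 46.3% of genes only, those with few reads, and reads only up to a common factor. No paired analysis was possible because the table's libraries carry no replicate numbers. Against 6359 calls (4543 positive, 1816 negative, 71.4% positive), an adjusted p under 0.01 left 1625 (993, 632, 61.1%). Centring on the median of genes with reads in both groups gave 5839 (2874, 2965, 49.2%) or 4142 (1199, 2943, 28.9%) by the order of the variances, and centring on that of genes without recovered reads 5897 (3096, 2801, 52.5%) or 4341 (1499, 2842, 34.5%). Student's p made the positive share 74.6%, a fold of at least 2 made it 74.3%, and genes with reads in both groups but none recovered 67.3%. These hold the genes with over 200 reads in a library, mixed with genes of fewer reads whose recovery failed. Centred values turned Mettl3 (adjusted p 0.074 or 0.17 by the order of the variances, on the first median), Ndufs1 (0.022 or 0.059, and 0.044 or 0.11 on the second median) and Psmc6 (0.0035 or 0.012, and 0.0036 or 0.016) negative. Igf2bp2, Hnrnpa2b1, Ythdc2, Ythdf3, Mtor (adjusted p = 0.054 or 0.082), Foxa1 (0.057 or 0.11) and Lfng (0.051 or 0.064) kept their sign and lost their call on the first median under both orders. Of the 152 genes tabulated by name, 12 lost their call with the same sign under the first and 45 under the second order, among them 5 writers, Sox2, Itga3 and Neat1 (0.075) under the second only. Krt13 gained a call under both orders, and Krt5 and Epcam under the second. Among the 8697 genes with recovered values 820 were called when adjusted over these alone. Leaving out each library gave 0 to 336, fewer in each of 6 cases, with 336, 102 and 199 without a library of the first group and 25, 0 and 9 without one of the second, where fewer degrees of freedom remain. On the log2 scale it was 1468 and 1372 with pseudocounts of 0.1 and 1, and 1142 with a pseudocount of 10. Of the 21 lists called, 9 passed with a correlation of 0.05 and 3 with 0.1. On log2 fold changes 10 lists passed, 9 of them among the 21 and the other the red blood cell markers (adjusted p = 0.014), and over genes without recovered reads 13 passed, 12 of them among the 21. More lists passed on ranks and with Student's p, 24 each, all 21 among them, and 18 passed over genes with reads in both groups, 17 of them among the 21. The DNA damage (adjusted p = 0.02 and 0.039), endothelial (0.019 and 0.049) and junction (0.021 and 0.032) lists were called on ranks and with Student's p only. The Notch list was called over genes with reads in both groups (0.043) and over those without recovered reads (0.031). The cause of these differences was not tested. Depth limits genes at zero in one group, whose fold is set by the added 1.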

Other observations

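The tests of symbol families and the correlations with length were chosen after the data were seen. Symbols that start alike were grouped into 100 families of at least 12 genes outside the fixed lists, of which 13 had an adjusted p under 0.05 (cameraPR, correlation 0.01) and 2 with a correlation of 0.05. These 2 were the mitochondrial ribosomal proteins. Of 49 Mrpl genes 27 were called negative and 10 positive in the authors' deposited table (median -0.77; cameraPR, adjusted p = 1.7e-06, and 0.014 with a correlation of 0.05), with Mrpl20 at -2.13 (adjusted p = 0.002) and Mrpl43 at 1.18 (adjusted p = 0.0028). Of 29 Mrps genes 15 were called negative and 6 positive in the authors' deposited table (median -0.67; cameraPR, adjusted p = 3.2e-05, and 0.014 with a correlation of 0.05), with Mrps24 at -2.09 (adjusted p = 0.0043) and Mrps2 at 2.45 (adjusted p = 0.0029). Lsm genes, which encode RNA-binding ring proteins, were called negative in 6 of 13 cases and positive in 2 in the authors' deposited table, with Lsm8 at -2.39 (adjusted p = 0.0032; family adjusted p = 0.0075, and 0.11 with a correlation of 0.05). The other families called as lower than other genes were the tetraspanin genes Tspan, Tmem, the keratin genes Krt outside the fixed lists, Timm and Fkbp. In the authors' deposited table Tspan had 0 positive and 5 negative calls of 17, and Tmem 33 and 38 of 173. Krt had 1 and 3 of 30, Timm 2 and 6 of 14 and Fkbp 1 and 4 of 13. The median of Tmem was 0.05, so it was lower than other genes but not negative. In the order named, cameraPR gave the families adjusted p of 0.0099, 0.013, 0.031, 0.04 and 0.049. With a correlation of 0.05 their adjusted p was 0.14, 0.36, 0.25, 0.24 and 0.25 in this order.

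On the positive side stood the ubiquitin-specific protease genes, with 28 of 45 Usp genes called positive and 0 negative in the authors' deposited table (median 2.07; cameraPR, adjusted p = 0.0023, and 0.14 with a correlation of 0.05), such as Usp16 at 2.96 (adjusted p = 0.0029). Zbtb transcription factor genes had 22 of 41 called positive and 0 negative in the authors' deposited table (median 2.64; adjusted p = 0.007, and 0.19 with a correlation of 0.05), with Zbtb41 at 2.59 (adjusted p = 0.00095). Klhl genes, encoding substrate adaptors of ubiquitin ligases, had 13 of 25 called positive in the authors' deposited table (median 2.54; adjusted p = 0.0075, and 0.14 with a correlation of 0.05). Centrosomal Cep genes, such as Cep350 at 3.29 (adjusted p = 0.0011), had 19 of 39 called positive and 2 negative, and kinesin Kif genes, such as Kif3b at 3.89 (adjusted p = 0.0058), 10 of 31 and 0 in the authors' deposited table (family adjusted p = 0.019 and 0.031, and 0.25 for both with a correlation of 0.05).

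Gene length went with the fold change. Across the 13321 protein-coding genes with reads in both groups, Spearman's rho of genomic span and log2 fold change of the authors' deposited table was 0.31, and genes are not independent replicates. The tenth of genes with the shortest spans (median 2706 nt) had a median of -0.38 and the tenth with the longest (median 184605 nt) 1.81 in the authors' deposited table. Over recovered genes rho with exonic length was 0.34.

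The low values of the ribosomal protein genes were set against gene length as a possible explanation. The 1368 other protein-coding genes with spans of 1591 to 5548 nt had a median log2 fold change of -0.05 in the authors' deposited table, 2.72 above that of the ribosomal protein genes (bootstrap interval 2.49 to 3.0), which argues against short span as the whole cause. High abundance of these transcripts stays open, since the table gives no levels for them. Among recovered genes, the 397 with an exonic length of up to 500 nt had a median of -0.03. The 827 with 500 to 1000 nt had -0.26, and both lie above the -2.77 of the ribosomal protein genes. Recovered genes are those with few reads, and the ribosomal protein genes were not matched by exonic length. Exonic length therefore stays open as well. No biological explanation was tested, because the groups compared are not named.

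The high values of the Zfp genes were treated alike. The median of the 6260 other protein-coding genes with spans of 7864 to 46407 nt minus that of the Zfp genes was -2.35 (bootstrap interval -2.59 to -2.18), which argues against span as the whole cause. These spans are not long ones, and even the tenth with the longest spans (median 184605 nt) had a median of 1.81. A set matched by span could thus hardly reach the Zfp median of 3.13, so this outcome was largely set beforehand. Exonic length was not matched for Zfp genes and stays open. A candidate explanation is that the first group is the m6A-bound fraction: the list of transcripts described as m6A-modified lay 1.05 above all genes. Some lists not chosen for m6A lay higher, such as chromatin regulators (1.41) and EGFR genes (1.19), and others lower, such as Wnt genes (0.89). The height is thus not particular to the m6A-modified list. The ribosomal protein median, also laid out for this explanation, lay 3.73 below that of all genes. Mitochondrially encoded genes, laid out with it, had no members to examine. A comparison of Input with Unbound would give the same signs, so the signs cannot tell the fractions apart. The sizes of the fold changes were not weighed for this. Reads shared between Zfp genes stay open.

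The excess of positive calls, 71.4%, may come from the scaling to library totals, in which a few abundant transcripts of one group lower all other values. After centring, the positive share was 49.2% or 28.9%, depending on which group holds the larger variance in genes without recovered values. The higher share belongs to the order in which the group with the higher mean has the higher variance, which held for 76.6% of the 1632 called genes with reads in both groups and recovered values. Whether it holds as often in the other genes is not known. Centring on the median of the same genes sets their balance by itself, so these shares decide nothing and the scaling stays open as a cause. Few reads stay open in part: the test was laid out for genes with over 200 reads in a library but could only be run on genes without recovered reads, which include some with fewer. Of 4667 such calls 65.4% were positive (95% Wilson interval 64.0% to 66.7%), above the 60% set for this cause. The 65% set against it lies under the share but inside its interval. By the share alone, the rule first applied, few reads would not be the cause. The rule of judging by the interval was chosen after the share was seen. Adjusted over these genes alone, 67.3% of 5604 calls were positive (66.0% to 68.5%), beyond 65%. This counts against few reads as the whole cause, but genes with fewer reads are among these genes in an unknown number, so it does not decide. Of the 1692 calls with recovered reads, which are those with fewer reads, 1493 (88.2%) were positive, so few reads went with a larger share and may add to the excess. Of the 10 splits of the 6 libraries, the real one called 820 recovered genes and the highest of the others 0, 1 split of 10 as large, and so few splits cannot give a share under 0.05.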
